A study of Mus musculus with 12 samples.

How the data were processed

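RNA of mouse ES cells was measured on 12 one-colour arrays: 2 reporter lines, 2 arms (FBS and serum-free) and days 0, 3 and 10, with 1 array per combination. Each array held 45018 spots, 43379 of them not controls, and the arrays lay on 3 slides of 4. Slide 1 held FBS Dazl-GFP at every day and FBS Stella-GFP at day 0. Slide 2 held FBS Stella-GFP at days 3 and 10 and serum-free Dazl-GFP at days 0 and 3. Slide 3 held serum-free Dazl-GFP at day 10 and serum-free Stella-GFP at every day.

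The deposited spot intensities came from Agilent Feature Extraction with local background subtraction and spatial and multiplicative detrending, and with a small surrogate where the signal was not above background, per the file headers. The deposited raw mean intensity, local background intensity and background-subtracted intensity of each spot were used for alternatives, and 0 or 1 marks of spots well above background or irregular were deposited beside them. The series table that the authors deposited for the series names no processing. From its values, it holds the background-subtracted intensity divided by the array median (each array has a median of 1), with a floor of 0.1 reached by 3214 to 5600 values per array.

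Probes were named from the RefSeq table (22951 of 41174 probes), from the authors' table (7527) or from the file's own name (10696), giving 27716 genes. Spots of a probe were averaged on the log2 scale after subtracting each array's 75th percentile. The probe with the highest mean stood for a gene, and genes with a spot well above background on at least 2 arrays were kept, 21338 in all. Across arrays the median CV of replicate spots was 5.8% to 9.7% and the r² of the spike-ins 0.993 to 0.998.

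R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8) was used, and figures were drawn with matplotlib 3.10.9. A linear model of the 6 groups plus the cell line was fitted to all 12 arrays, so that the groups share 1 estimate of the spread (5 residual degrees of freedom, prior degrees of freedom 2.53). Contrasts gave the arm differences at each day, the time courses in each arm and the difference of the day 10 changes. A model of medium, day and line gave the difference over all days, and a term of line by medium gave the interaction. P-values were moderated by eBayes and adjusted by Benjamini and Hochberg over the genes of a comparison, at 0.05. The labels' replicate numbers 1 and 2 are the Stella-GFP and Dazl-GFP lines, which pairs the arrays. Over 15 pairs of groups the line differences correlated across genes at -0.05 to 0.571 (median 0.156, above 0.1 in 13).

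A gene whose probe was well above background in 1 group of a comparison and on no array of the other is given as at least a fold. That is the mean of the detected group against the other group's signals, each raised to its array's floor, the lowest log2 signal of a spot well above background on that array. It was used in place of the fitted change. Where only some arrays of a group measured a named gene, the change is the fitted value and their number is given.

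The lists, 28 with 351 genes, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists are naive pluripotency, general pluripotency, primed and formative pluripotency, MEK-ERK targets, Wnt and beta-catenin targets, LIF-STAT3 targets, BMP targets, Nodal targets, serum response, germ cell genes, DNA methylation and demethylation, 2-cell stage genes, neuroectoderm, mesendoderm, primitive endoderm, trophoblast, fibroblast markers, sterol synthesis, fatty acid synthesis, glycolysis, hypoxia, ATF4 targets, p53 targets, cell division, antioxidant response, retinoid response, imprinted genes and Y-linked genes. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For camera 15 genes with an irregular spot were left out. Members counted as changed passed 0.05 over all genes, and a count adjusted over the members of the list alone is given beside it. Genes named are, per comparison, the up to 8 highest and 8 lowest changes among genes past 0.05 with the same sign in both lines (fewer where described briefly), without clone and accession names, 2 to 4 members of each list described, and Dazl, Dppa3, Nanog, Pou5f1 and Tet1 to Tet3 always, since the series title names Dazl and TET. Some genes that this rule selects are not reported here. In the line comparison the same-sign condition has no meaning and was not used.

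Alternatives were quantile normalization, normexp background correction (offset 50), the authors' table, no filter, only genes above background on all 12 arrays, all probes separately, no cell line block, the slide as a block, a variance trend, only the 4 arrays compared, the mean of the contrasts within a day and leaving out each array in turn. Chosen after seeing the data were normexp with a local background above 10 times the array's median replaced by that median, the mean fibroblast marker level as a covariate, leaving out the day 3 arrays, and gene lists for the interferon response, macrophages and the aryl hydrocarbon receptor. Splits of the 12 arrays into 6 and 6 (100 drawn of 462, seed 1) were fitted the same way for the comparisons of 6 against 6.

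The procedure was tested on simulated data with 200 changed genes and 1 shifted list of 15. In the 7 comparisons of 2 arrays against 2 it recovered 87.9% to 98.5% of the genes changed 8-fold, 77.6% to 85.1% at 4-fold and 6% to 17.9% at 2-fold. The shares were 98.5%, 97% and 74.6% over all days, 98.5%, 98.5% and 79.1% between the lines and 89.4%, 49.3% and 0% (of 67 genes, by limma) for line by arm. For the difference of the day 10 changes they were 86.4%, 41.8% and 1.5%. Comparisons had 2 to 16 false calls and 0 wrong directions. These rates need not hold on real arrays.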

Results

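The series measured RNA in mouse embryonic stem (ES) cells on 12 one-colour arrays, 1 array per cell line, arm and day. The labels name a pair of reporter lines, Stella-GFP and Dazl-GFP, called after the germ cell genes Dppa3 (Stella) and Dazl. Cells grew with leukemia inhibitory factor (LIF) on irradiated mouse embryonic fibroblasts, which serve as feeder cells, in medium with 15% fetal bovine serum (FBS) or in serum-free B27N2 medium. For the 2i experiments the labels give the MEK inhibitor PD0325901 at 1 µM and the GSK3β inhibitor Kenpaullone at 5 µM, and cells were taken at days 0, 3 and 10. The 6 groups are the FBS arm and the serum-free arm, which the labels call the 2i condition, at each day, with 2 arrays per group. The labels do not say whether the FBS arm received the inhibitors at days 3 and 10, nor what the serum-free cells at day 0 had received. On the 12 arrays 64% to 74.4% of the spots lay well above background, the 75th percentile of the signal was 454 to 947 intensity units, and the number of arrays limits the precision.

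Changes are log2 differences of limma fits with their SE, from 1 array of each line per group, and each gene named as having risen, fallen or differed between groups moved the same way in both lines. The p-values measure only the spread between these samples. Of 27716 genes on the array 21338 were tested. Each list was tested with camera, and the median given with a list is over all its measured genes, and no list's call held in any comparison with an estimated correlation.

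The first comparison asks how the arms differed at day 0. The chemokine Ccl5 was higher in the serum-free arm by 4.02 (SE 0.23, adjusted p = 0.0022), as were Pglyrp1, a protein that binds bacterial cell walls, by 4.16 (SE 0.52, adjusted p = 0.0232), and the protease inhibitor gene Serpina3g by 3.51 (SE 0.53, adjusted p = 0.0306). Pglyrp1 was well above background on 1 of the 2 FBS arrays. Iigp1, an interferon-inducible GTPase, was at least 9.14-fold higher (adjusted p = 0.0443) and Serpina3n at least 7.75-fold higher (adjusted p = 0.0232), though with normexp as planned they turned to -0.20 and -0.37. Lower were Figla, an oocyte transcription factor, at least 2.82-fold (adjusted p = 0.00171), the growth factor Fgf18 by -2.72 (SE 0.28, adjusted p = 0.0152) and Prl2c5, of the prolactin family, by -2.87 (SE 0.27, adjusted p = 0.0132). Tet2, a 5-methylcytosine oxidase, was higher by 1.37 (SE 0.17, adjusted p = 0.0232), with 0.998 (adjusted p = 0.0485) and 0.80 (adjusted p = 0.147) at its other probes, while Dazl (-0.48), Dppa3 (1.04), Nanog (0.20), Pou5f1 (-0.43), Tet1 (-0.03) and Tet3 (-0.73) did not pass.

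Of the 14 measured naive pluripotency genes 2 were higher at day 0 and 12 did not pass, with 5 higher adjusted over the list alone, Nr5a2 by 1.08 and Zfp42 by 0.80. Camera put the list up (median 0.60, adjusted p = 0.000638; adjusted p = 0.362 with an estimated correlation). Of 13 primitive endoderm genes, which mark the yolk sac lineage, 1 was higher and 12 did not pass, with 6 higher adjusted over the list alone, and Sox7 was higher by 1.82 (SE 0.29, adjusted p = 0.0359). Their median was 1.17 (camera adjusted p = 0.000456, or 0.473 with an estimated correlation). Of 7 Nodal targets Lefty1 alone was lower, by -2.40 (SE 0.28), and 6 did not pass, with 5 lower adjusted over the list alone. Their median was -0.92 (camera adjusted p = 0.0013, or 0.302 with an estimated correlation). Camera also put down 4 other lists: ATF4 targets (1 of 14 lower, Chac1 by -2.28, 13 not passing, 8 lower adjusted over the list alone), retinoid response genes (1 of 10 lower, Crabp2 by -1.19 and well above background on 1 of the 2 serum-free arrays, 9 not passing, 5 lower adjusted over the list alone), serum response genes (2 of 17 lower, Ankrd1 by -1.92 and Cnn1 by -1.39, 15 not passing, 2 lower adjusted over the list alone) and imprinted genes. Their medians were -0.61, -1.39, -0.43 and -0.40, and their adjusted p-values were 0.00167, 0.0181, 0.0206 and 0.0247, with adjusted p = 0.473, 0.302, 0.473 and 0.302 with an estimated correlation. Among 17 imprinted genes 1 was higher, Igf2 by 1.33, and 1 was lower, Cdkn1c by -1.87, with 1 higher and 6 lower adjusted over the list alone.

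In all, 406 genes differed at day 0 (limma, adjusted p under 0.05), 219 higher and 187 lower in the serum-free arm, 357 of them by at least 2-fold. With the slide as a block limma called 0 genes (2822 at an unadjusted p under 0.05), and no slide held both arms at day 0. The count was 3 without replicate 1 or 2 of the serum-free day 0 group, 68 without either of its day 3 arrays and 127 or 229 without replicate 1 or 2 of the FBS day 0 group, 138 without an FBS day 3, 166 without an FBS day 10 and 147 without a serum-free day 10 array. The count was 143 without the cell line block, 197 with no filter on dim genes, 898 with a variance trend and 1000 with normexp background correction on repaired backgrounds, and the share higher was 68.8% in the authors' table and 64.1% after quantile normalization against 53.9%.

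At day 3 the comparison asks how the arms differed early in the treatment. Of 19 fibroblast genes, which mark feeder cells, 16 were lower in the serum-free arm and 3 did not pass, with 17 lower adjusted over the list alone. S100a4 was lower by -4.86 (SE 0.31), the mesenchymal regulator Twist2 by -4.23 (SE 0.22), the surface protein Thy1 by -4.26 (SE 0.34) and the actin-binding Tagln by -3.41 (SE 0.27), with adjusted p at most 0.00152. The list's median was -2.08 (camera adjusted p = 2.8e-08, or 0.364 with an estimated correlation). Its link to the lists described next stays open. Serum response genes were lower for 13 of 17, with 4 not passing and 14 lower adjusted over the list alone. Their median was -2.19 (camera adjusted p = 2.49e-08, or 0.364 with an estimated correlation). Among them were Egr2 (-4.63), the contractile gene Myl9 (-4.38), and Fos (-4.21), an immediate early transcription factor.

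Primitive endoderm genes were higher in the serum-free arm at day 3 for 8 of 13, with 5 not passing and 10 higher adjusted over the list alone. Their median was 2.01 (camera adjusted p = 1.92e-06, or 0.364 with an estimated correlation). The endocytic receptor Cubn was higher by 3.85 (SE 0.93), the basement membrane genes Col4a1 by 3.02 (SE 0.50) and Col4a2 by 2.56 (SE 0.54), and the endoderm factor Sox17 by 2.87 (SE 0.47). LIF-STAT3 targets were lower for 6 of 11, with 5 not passing and 6 adjusted over the list alone: Bcl3 by -2.43 (SE 0.15), Socs3, a feedback inhibitor of STAT3, by -2.31 (SE 0.15) and Osmr by -2.21 (SE 0.35), which turned to 0.14 with the fibroblast level as a covariate. Their median was -1.25 (camera adjusted p = 0.0168, or 0.364 with an estimated correlation). Neuroectoderm genes were lower for 6 of 11, with 5 not passing and 7 adjusted over the list alone, led by Hes5 (-2.18), Tubb3 (-2.06) and Map2 (-2.01). Their median was -1.65 (camera adjusted p = 0.00877, or 0.364 with an estimated correlation). ATF4 targets, genes of the amino acid stress response, were lower for 8 of 14, with 6 not passing and 11 lower and 1 higher adjusted over the list alone, including Chac1 (-2.44) and Trib3 (-2.15), while Slc7a11 was not well above background in either arm. Their median was -0.80 (camera adjusted p = 0.00877, or 0.461 with an estimated correlation). Sterol synthesis genes were higher for 6 of 19, with 13 not passing and 6 higher and 2 lower adjusted over the list alone, Stard4 by 2.09 and Nsdhl by 1.06, though Stard4 reversed to -0.58 when all probes were tested separately. Their median was 0.25 (camera adjusted p = 0.00442, or 0.364 with an estimated correlation). Naive pluripotency genes were higher for 1 of 14, Nr0b1 by 1.19 (SE 0.19), with 13 not passing and 1 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 0.0128, or 0.364 with an estimated correlation).

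Camera called no other list at day 3. Of 17 MEK-ERK targets 5 were lower, among them Fos (-4.21), Egr1 (-3.10), Etv4 (-1.32) and Ccnd1 (-1.27), 1 was higher and 11 did not pass, with 8 lower and 1 higher adjusted over the list alone (median -0.81, adjusted p = 0.233). Of 13 Wnt and beta-catenin targets 5 were lower and 8 did not pass, also 5 adjusted over the list alone, with Sp5 at -3.90 (median -0.42, adjusted p = 0.233). Of 12 primed and formative pluripotency genes Otx2 (1.72) and Dnmt3a (1.06) were higher and 3 were lower, among them Pou3f1 (-2.72) and Fgf5 (-1.90), with the same counts adjusted over the list alone. The list's median (0.12) and test (up, adjusted p = 0.683) differed in sign from its mean (-0.12). Outside the lists, Il1rl1, the receptor of interleukin 33, was at least 40.5-fold lower (adjusted p = 0.000908). Among the lowest were the lysozyme genes Lyz1 at -6.09 (SE 0.80) and Lyz2 at -5.79 (SE 0.76), and Ctss, a lysosomal protease, at -4.96 (SE 0.42), with Lyz1 and Ctss well above background on 1 of the 2 serum-free arrays. Higher was the hexokinase-like gene Hkdc1 at 4.64 (SE 0.46, adjusted p = 0.00205), while Capn6 was at least 8.96-fold higher (adjusted p = 0.00152). Tet2 was higher by 1.05 (SE 0.17, adjusted p = 0.008), with 0.59 (adjusted p = 0.0504) and 2.01 (adjusted p = 0.00492) at its other probes, and Dazl (0.75), Dppa3 (-0.06), Nanog (0.31), Pou5f1 (-0.07), Tet1 (0.22) and Tet3 (0.00) did not pass.

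At day 3, 4814 genes differed, 1918 higher and 2896 lower in the serum-free arm, and 2858 of them by at least 2-fold (limma), with 4813 of the 4814 moving the same way in both lines. With the mean fibroblast level as a covariate limma called 0 genes (5444 unadjusted). The LIF-STAT3 median turned to 0.02 and the fibroblast median, by construction, to 0.055. That level nearly repeats the arm at day 3, so this decides nothing on feeder cells. With the slide as a block limma called 1453. Within slide 2, across the lines, the medians of called lists stayed within 1.5 times (fibroblast markers -2.85) but for sterol synthesis (0.44). The count was 1693 or 1065 without replicate 1 or 2 of the FBS day 3 group, 1201 or 1078 without those of the serum-free group, 0 on the 4 day 3 arrays alone (7269 unadjusted), 7530 over all probes and 9634 (20.3% higher) with normexp on repaired backgrounds, and quantile normalization moved the median of all genes from -0.21 to -0.08 and the share higher from 39.8% to 50.8%.

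**Figure D1:**
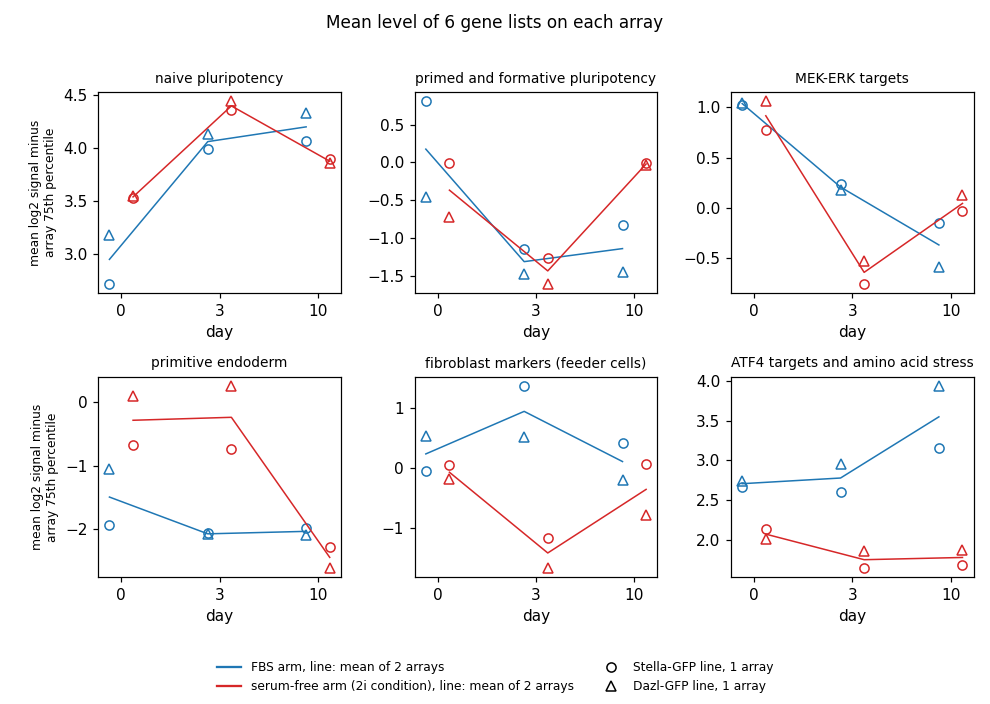
Mean level of 6 gene lists on each array (vertical axis, log2 signal relative to the array's 75th percentile) by day (horizontal axis, days at equal spacing) in the FBS and serum-free arms. Circles are Stella-GFP, triangles Dazl-GFP, and lines join the means of the 2 arrays; the fibroblast markers had their lowest group mean, -1.41, in the serum-free arm at day 3.

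At day 10 the comparison asks how the arms differed at the end of the course. ATF4 targets were lower in the serum-free arm for 9 of 14, with 5 not passing and 13 lower adjusted over the list alone. Their median was -1.28 (camera adjusted p = 3.56e-12, or 0.224 with an estimated correlation). Chac1, which degrades glutathione, was lower by -4.38 (SE 0.42, adjusted p = 0.00586), the stress regulator Trib3 by -3.67 (SE 0.24, adjusted p = 0.00409) and the one-carbon enzyme gene Mthfd2 by -2.22 (SE 0.30, adjusted p = 0.0116), and the cystine transporter gene Slc7a11 was at least 3.21-fold lower (adjusted p = 0.013). Outside the list, the stress hormone gene Fgf21 was at least 14.8-fold lower (adjusted p = 0.00586), and the stress factors Atf3 and Nupr1 were lower by -4.87 (SE 0.32) and -4.36 (SE 0.40). Stra8, a retinoic acid target needed for meiotic entry, was lower by -5.17 (SE 0.53, adjusted p = 0.00596), while Mmp3, a matrix protease, was higher by 5.21 (SE 1.05, adjusted p = 0.0345), as was the interferon-inducible GTPase gene Irgm1 by 3.88 (SE 0.69). Mmp3 was well above background on 1 of the 2 FBS arrays.

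Primed and formative pluripotency genes were higher in the serum-free arm at day 10 for 4 of 12, with 8 not passing and 5 higher adjusted over the list alone: the DNA methyltransferase genes Dnmt3b by 2.69 (SE 0.35) and Dnmt3a by 1.48 (SE 0.29), and the growth factor Fgf5 by 1.89 (SE 0.32). Their median was 0.86 (camera adjusted p = 0.000891, or 0.24 with an estimated correlation). Naive pluripotency genes were lower for 1 of 14, Tcl1 by -1.31 (SE 0.25), with 13 not passing and 4 lower and 1 higher adjusted over the list alone. Their median was -0.29 (camera adjusted p = 0.0166, or 0.359 with an estimated correlation). Germ cell genes were lower for 1 of 21, the piRNA factor Mov10l1 by -1.62 (SE 0.18) and well above background on 1 of the 2 serum-free arrays, with 20 not passing and 6 lower adjusted over the list alone. Their median was -0.63 (camera adjusted p = 5.68e-05, or 0.357 with an estimated correlation). Dazl was at -1.85 (SE 0.62, adjusted p = 0.128) and Nanog at -0.71 (SE 0.19, adjusted p = 0.0704), so neither passed, nor did Dppa3 (0.77), Pou5f1 (-0.23), Tet1 (0.35), Tet2 (-0.17) or Tet3 (-0.91). Nodal targets were lower for 4 of 7, with 3 not passing and 4 adjusted over the list alone, among them Lefty2 (-1.96), and the list had a median of -0.75 (camera adjusted p = 0.000472, or 0.144 with an estimated correlation). Serum response genes were lower for 4 of 17, with 13 not passing and 8 lower adjusted over the list alone, Myl9 by -1.57 and Tagln by -1.57. Their median was -0.77 (camera adjusted p = 5.68e-05, or 0.24 with an estimated correlation). Fibroblast markers were lower for 3 of 19, with 16 not passing and 8 lower adjusted over the list alone, S100a4 by -2.19 and Tagln by -1.57. Their median was -0.36 (camera adjusted p = 0.00928, or 0.505 with an estimated correlation), and 0.135 with their own level as a covariate, by construction.

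Camera called 7 other lists at day 10. Fatty acid synthesis genes were lower for 3 of 10, with 7 not passing and 5 lower adjusted over the list alone, led by the desaturase gene Scd2 (-1.22) and Me1 (-1.11), with a median of -0.40 (adjusted p = 0.00065, or 0.144 with an estimated correlation). LIF-STAT3 targets were lower for 3 of 11, with 8 not passing and 4 lower adjusted over the list alone, Socs3 by -1.42 and Bcl3 by -1.36. Their median was -0.28 (adjusted p = 0.0166, or 0.37 with an estimated correlation), and it turned to 0.10 with the fibroblast level as a covariate. Retinoid response genes were lower for 3 of 10 and higher for 1, with 6 not passing, 4 lower and 1 higher adjusted over the list alone, with Stra8 at -5.17. Their median was -0.84 (adjusted p = 0.0166, or 0.224 with an estimated correlation). Of 10 hypoxia genes Vegfa alone was lower, by -3.86 (SE 0.27), with 9 not passing and 4 lower and 1 higher adjusted over the list alone. Their median was -0.46 (adjusted p = 0.0166, or 0.455 with an estimated correlation). Of 13 primitive endoderm genes Lama1 alone was lower, by -1.67, also 1 adjusted over the list alone, with 12 not passing. Their median was -0.63 (adjusted p = 0.032, or 0.505 with an estimated correlation). The median of that list was 0.03 without replicate 2 of the serum-free day 10 group. Of 19 sterol synthesis genes 0 passed in limma, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05, with Dhcr7 at -0.77 and Msmo1 at -0.60, and camera put the list down. Their median was -0.17 (adjusted p = 0.0166, or 0.359 with an estimated correlation). Wnt and beta-catenin targets were higher for 2 of 13, with 11 not passing and 5 higher adjusted over the list alone, Sp5 by 2.42 and T by 0.90. Their median was 0.90 (adjusted p = 0.0263, or 0.24 with an estimated correlation).

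At day 10, 1202 genes differed, 429 higher and 773 lower in the serum-free arm, and 952 of them by at least 2-fold (limma). With the slide as a block limma called 0 genes (2477 at an unadjusted p under 0.05), and no slide held both arms at day 10. It called 344 or 15 without replicate 1 or 2 of the FBS day 10 group and 443 or 19 without those of the serum-free group, 727, 733 or 766 without 1 serum-free day 0, FBS day 3 or serum-free day 3 array, and 0 on the 4 day 10 arrays alone (4162 unadjusted). The count was 613 without the cell line block, 799 with no filter on dim genes and 781 with the fibroblast level as a covariate, and the share higher, 35.7%, was 21.9% in the authors' table and 48.6% with normexp on repaired backgrounds.

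The next comparisons ask what changed with time in each arm. From day 0 to day 3 in the serum-free arm, MEK-ERK targets, genes that growth factor signalling turns on, fell for 9 of 17, with 8 not passing and 11 lower adjusted over the list alone. Their median was -1.23 (camera adjusted p = 7.13e-06, or 0.19 with an estimated correlation). Etv4 fell by 4.53 (SE 0.26, adjusted p = 0.00153), the feedback inhibitor Spry4 by 3.94 (SE 0.29, adjusted p = 0.00189), Myc by 4.14 (SE 0.68) and the ERK phosphatase gene Dusp6 by 2.74 (SE 0.37). Naive pluripotency genes rose for 5 of 14, with 9 not passing and 10 higher adjusted over the list alone: Tbx3 by 2.04 (SE 0.42), Pecam1 by 1.23 (SE 0.19), Tcl1 by 1.22 (SE 0.25), Klf4 by 1.06 (SE 0.28), and Nanog, a core pluripotency factor, by 0.96 (SE 0.18, adjusted p = 0.0186). Their median was 0.96 (camera adjusted p = 3.15e-05, or 0.19 with an estimated correlation). Wnt and beta-catenin targets fell for 7 of 13, with 6 not passing and 11 lower and 1 higher adjusted over the list alone, Sp5 by -3.40 and Dkk1 by -2.42, and Cdx2 was at least 3.79-fold lower. Their median was -1.86 (camera adjusted p = 0.000262, or 0.19 with an estimated correlation).

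Fibroblast markers fell in the serum-free arm by day 3 for 9 of 19, with 10 not passing and 13 lower adjusted over the list alone, S100a4 by -3.61, Thy1 by -2.67 and Tagln by -2.23. Their median was -1.29 (camera adjusted p = 4.26e-06, or 0.412 with an estimated correlation). Imprinted genes fell for 8 of 17, with 9 not passing and 10 adjusted over the list alone, Dlk1 by -4.06 and Cdkn1c by -2.96. Their median was -0.96 (camera adjusted p = 0.0031, or 0.19 with an estimated correlation). Germ cell genes fell for 8 of 21 and rose for 1, with 12 not passing and the same counts adjusted over the list alone, Mael by -1.96 and the germ cell helicase gene Ddx4 by -1.67, against Prdm1 at 2.20. Their median was -0.56 (camera adjusted p = 0.0134, or 0.464 with an estimated correlation). Primed and formative pluripotency genes fell for 3 of 12, with 9 not passing and 6 adjusted over the list alone, Pou3f1 by -3.53, Dnmt3b by -2.82 and Fgf5 by -2.70. Their median was -0.49 (camera adjusted p = 0.022, or 0.412 with an estimated correlation). Cell division genes fell for 4 of 14, with 10 not passing and 5 adjusted over the list alone, Ccne1 by -1.94 and Ccne2 by -1.45. Their median was -0.47 (camera adjusted p = 0.00116, or 0.221 with an estimated correlation). Fatty acid synthesis genes rose for 3 of 10, with 7 not passing and 6 adjusted over the list alone, Elovl6 by 0.78 and Fads1 by 0.72. Their median was 0.55 (camera adjusted p = 0.00524, or 0.19 with an estimated correlation). Camera also put serum response genes down (4 of 17 fell, 1 rose, the same adjusted over the list alone, Myl9 by -3.01, adjusted p = 0.0208, or 0.446 with an estimated correlation) and sterol synthesis genes up (2 of 19 rose, 1 adjusted over the list alone, Fdft1 by 0.76, adjusted p = 0.028, or 0.446 with an estimated correlation). Cyp1a1, a target of the aryl hydrocarbon receptor, was at least 40.7-fold higher (adjusted p = 0.00378), and the phospholipase gene Pla1a rose by 3.90 (SE 0.38). Tnfsf11 was at least 10.1-fold lower (adjusted p = 0.00189) and Il1rl1 at least 15.9-fold (adjusted p = 0.00153), and Tmem54 fell by 4.91 (SE 0.30). Dazl (1.37, while its other probe gave 1.72 at adjusted p = 0.0442), Dppa3 (1.60), Pou5f1 (-0.21), Tet1 (-0.01), Tet2 (0.15) and Tet3 (-0.66) did not pass.

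By day 3 in the serum-free arm 2955 genes had changed, 1262 up and 1693 down, 1923 of them by at least 2-fold (limma). A slide block gave 2618. Within slides 2 (Dazl-GFP) and 3 (Stella-GFP) the medians of called lists stayed within 1.5 times, but for germ cell genes on slide 2 (-0.96) and primed and formative genes on slide 3 (-0.81). The count was 762 or 232 without replicate 1 or 2 of the serum-free day 0 group, 438 or 573 without those of its day 3 group, 1178 with the fibroblast level as a covariate and 4594 over all probes, where Stard4 turned to -0.51.

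By day 10 in the serum-free arm MEK-ERK targets were below day 0 for 6 of 17, with 11 not passing and 9 lower and 1 higher adjusted over the list alone. Their median was -1.07 (camera adjusted p = 0.000159, or 0.333 with an estimated correlation). Etv4 fell by 3.28 (SE 0.26, adjusted p = 0.00496) and Spry4 by 3.16 (SE 0.29, adjusted p = 0.00534). Primitive endoderm genes fell for 6 of 13, with 7 not passing and 11 adjusted over the list alone: Cubn by 4.76 (SE 0.93), Dab2 by 3.67 (SE 0.45), Sox7 by 2.70 (SE 0.29) and the lineage factor Gata6 by 2.63 (SE 0.45). Their median was -1.94 (camera adjusted p = 9.63e-10, or 0.333 with an estimated correlation). Germ cell genes fell for 7 of 21, with 14 not passing and 13 adjusted over the list alone, the piRNA genes Piwil2 by 2.00 (SE 0.20) and Mov10l1, well above background on 1 of the 2 day 10 arrays, by 1.84 (SE 0.18). Their median was -1.07 (camera adjusted p = 2.51e-08, or 0.333 with an estimated correlation). Imprinted genes fell for 5 of 17, with 12 not passing and 8 lower and 3 higher adjusted over the list alone, Phlda2 by -2.75 and Dlk1 by -2.35. Their median was -0.40 (camera adjusted p = 0.0115, or 0.333 with an estimated correlation). Fibroblast markers fell for 3 of 19, with 16 not passing and 3 adjusted over the list alone, S100a4 by -1.84 and Tagln by -1.26. Their median was -0.34 (camera adjusted p = 0.0449, or 0.659 with an estimated correlation). Of 14 cell division genes 0 passed in limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, with Ccne1 at -0.96 and Ccne2 at -0.51. Their median was -0.19 (camera adjusted p = 0.0115, or 0.421 with an estimated correlation). Cyp1a1 was at least 29.0-fold higher (adjusted p = 0.00888), the channel gene Trpm1 at least 6.86-fold higher (adjusted p = 0.00534), and Piwil4 at least 14.4-fold lower (adjusted p = 0.00534). Nanog (0.55, adjusted p = 0.124), Dazl (1.15), Dppa3 (0.41), Pou5f1 (-0.16), Tet1 (-0.12), Tet2 (-0.29) and Tet3 (-1.42) did not pass.

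By day 10 in the serum-free arm 1119 genes had changed, 464 up and 655 down, 903 of them by at least 2-fold (limma). Within slide 3 (Stella-GFP) the medians of called lists stayed within 1.5 times but for fibroblast markers (0.05) and primitive endoderm (-1.18). Blocking on the slide gave 11, and limma called 0 on the 4 arrays alone (5162 at an unadjusted p under 0.05) and 0 without replicate 2 of the serum-free day 0 group (2519 unadjusted). The count was 192 without replicate 1 of that group, 251 or 55 without replicate 1 or 2 of the day 10 group, 713 without either FBS and 725 without either serum-free day 3 array, 735 with no filter and 599 without the cell line block, and the share higher was 23.6% in the authors' table against 41.5%.

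From day 0 to day 3 in the FBS arm, naive pluripotency genes rose for 10 of 14, with 4 not passing and 10 adjusted over the list alone. Their median was 1.02 (camera adjusted p = 5.9e-05, or 0.31 with an estimated correlation). Dppa3 rose by 2.70 (SE 0.55, adjusted p = 0.0223), Tbx3 by 2.23 (SE 0.42), the Krüppel-like factors Klf2 by 1.77 (SE 0.30) and Klf4 by 1.54 (SE 0.28), and Nanog by 0.86 (SE 0.18, adjusted p = 0.0266). Primed and formative genes fell for 6 of 12, with 6 not passing and 7 adjusted over the list alone: Lef1 by 3.02 (SE 0.67), Dnmt3b by 2.96 (SE 0.35), Dnmt3a by 2.31 (SE 0.29) and Fgf5 by 2.28 (SE 0.32). Their median was -1.49 (camera adjusted p = 6.96e-06, or 0.31 with an estimated correlation). MEK-ERK targets fell for 6 of 17 and rose for 2, with 9 not passing and 8 lower and 2 higher adjusted over the list alone, Spry4 by -4.34 (SE 0.29) and Etv4 by -2.74 (SE 0.26) against Fos at 3.45 (SE 0.47). Their median was -0.62 (camera adjusted p = 0.000861, or 0.31 with an estimated correlation). Serum response genes rose for 9 of 17 and fell for 2, with 6 not passing and the same counts adjusted over the list alone, Egr2 by 3.78, Fos by 3.45 and Jun by 3.23. Their median was 1.05 (camera adjusted p = 0.00231, or 0.347 with an estimated correlation). Fibroblast markers rose for 2 of 19, with 17 not passing and 4 higher and 2 lower adjusted over the list alone, Col1a1 by 2.05 and Col5a1 by 1.39. Their median was 0.77 (camera adjusted p = 0.0486, or 0.684 with an estimated correlation), 1.68 in the Stella-GFP line, across slides, but 0.16 in the Dazl-GFP line, within slide 1.

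Germ cell genes in the FBS arm at day 3 fell for 9 of 21 and rose for 1, with 11 not passing and 15 lower and 3 higher adjusted over the list alone, the meiotic gene Sycp3 by -1.84 against Nanos3 at 1.67, and Taf7l was at least 6.58-fold and Sycp2 at least 1.82-fold lower. Nanos3 turned to -0.02 with normexp as planned and Sycp2 to 0.04 with normexp on repaired backgrounds. Their median was -1.20 (camera adjusted p = 6.96e-06, or 0.31 with an estimated correlation). LIF-STAT3 targets rose for 6 of 11 and fell for 1, with 4 not passing and 8 higher and 1 lower adjusted over the list alone, Tfcp2l1 by 1.64 and Bcl3 by 1.19 against Gbx2 at -3.02. Their median was 1.06 (camera adjusted p = 0.00313, or 0.347 with an estimated correlation). Imprinted genes fell for 8 of 17, with 9 not passing and 10 lower and 3 higher adjusted over the list alone, Rian by -3.13 and Dlk1 by -2.87, and Peg10 was at least 2.23-fold lower. Their median was -1.37 (camera adjusted p = 0.00093, or 0.278 with an estimated correlation). General pluripotency genes fell for 4 of 11, with 7 not passing and 5 lower and 1 higher adjusted over the list alone, Utf1 by -1.62 and the RNA-binding Lin28a by -1.57. Their median was -0.57 (camera adjusted p = 0.0176, or 0.31 with an estimated correlation). Of 5 measured 2-cell stage genes 0 passed in limma, 2 were lower adjusted over the list alone and 2 at an unadjusted p under 0.05, with Zscan4c at -2.48 and Tcstv1 at -1.63. Camera put the list down (median -1.14, adjusted p = 0.0459, or 0.56 with an estimated correlation), but its median was -2.35 in the Stella-GFP line, across slides, and 0.20 in the Dazl-GFP line, within slide 1. Of 10 retinoid response genes 0 passed in limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, with Stra6 at -1.96 and Stra8 at -1.36 (camera adjusted p = 0.0459, or 0.31 with an estimated correlation). Spic, a macrophage transcription factor, rose by 5.24 (SE 0.78) and the homeobox gene Rhox6 by 4.81 (SE 0.68), and Cyp1a1 was at least 14.4-fold higher. The retinoid receptor gene Rxrg fell by 4.85 (SE 0.30) and Tmem54 by 4.20 (SE 0.30). Dazl (0.15), Pou5f1 (-0.57), Tet1 (-0.27), Tet2 (0.47) and Tet3 (-1.39) did not pass.

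By day 3 in the FBS arm 2558 genes had changed, 1430 up and 1128 down, 1674 of them by at least 2-fold (limma). Within slide 1 (Dazl-GFP) the medians of the 11 called lists moved by over 1.5 times for general pluripotency (-0.167), MEK-ERK (-1.01), LIF-STAT3 (0.55), germ cell (-0.78) and retinoid response genes (-0.37) and the 2-cell and fibroblast lists above. A slide block gave 782, and limma called 0 on the 4 arrays alone (3757 at an unadjusted p under 0.05). The count was 315 or 490 without replicate 1 or 2 of the FBS day 3 group, 1596 without the cell line block and 8520 with normexp on repaired backgrounds, which put 83% higher against 55.9% and moved the median of all genes from 0.09 to 0.30.

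By day 10 in the FBS arm naive pluripotency genes were above day 0 for 10 of 14, with 4 not passing and 10 adjusted over the list alone. Their median was 1.36 (camera adjusted p = 2.24e-07, or 0.218 with an estimated correlation). Tbx3 rose by 3.17 (SE 0.42), Tfcp2l1 by 1.85 (SE 0.32), Pecam1 by 1.62 (SE 0.19) and Nanog by 1.46 (SE 0.18, adjusted p = 0.00422). MEK-ERK targets fell for 9 of 17 and rose for 1, with 7 not passing and 10 lower and 1 higher adjusted over the list alone: Spry4 by 5.72 (SE 0.29, adjusted p = 0.000485), Etv4 by 3.63 (SE 0.26), Myc by 3.47 (SE 0.68) and Dusp6 by 3.05 (SE 0.37). Their median was -1.11 (camera adjusted p = 0.000237, or 0.266 with an estimated correlation). Dazl, which encodes a germ cell RNA-binding protein, rose by 2.52 (SE 0.62, adjusted p = 0.0384), 1.06 in the Stella-GFP line and 3.98 in the Dazl-GFP line, with 1.90 at its other probe (adjusted p = 0.0352), and Tet2 rose by 1.25 (SE 0.17, adjusted p = 0.00565), with 0.81 (adjusted p = 0.0291) and 0.38 (adjusted p = 0.396) at its other probes. Dppa3 (0.68), Pou5f1 (-0.36), Tet1 (-0.50) and Tet3 (-1.25) did not pass. Dnmt3b fell by 3.24 (SE 0.35) and Dnmt3a by 2.69 (SE 0.29), and with Fgf5 (-3.67) and Pou3f1 (-2.46) they were among 5 of 12 primed and formative genes that fell, 5 also adjusted over the list alone. Their median was -1.22 (camera adjusted p = 0.00186, or 0.314 with an estimated correlation).

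ATF4 targets in the FBS arm rose by day 10 for 2 of 14, with 12 not passing and 7 adjusted over the list alone: Slc7a11 was at least 4.69-fold higher (adjusted p = 0.00407), though it turned to -0.49 with normexp as planned, and the asparagine synthetase gene Asns rose by 1.36 (SE 0.19). Their median was 0.55 (camera adjusted p = 0.00186, or 0.606 with an estimated correlation). Imprinted genes fell for 9 of 17 and rose for 1, with 7 not passing and 10 lower and 2 higher adjusted over the list alone, Dlk1 by -3.10 and Cdkn1c by -2.66 against Plagl1 at 3.05. Their median was -1.23 (camera adjusted p = 0.00186, or 0.218 with an estimated correlation). General pluripotency genes fell for 6 of 11, with 5 not passing and 6 lower and 1 higher adjusted over the list alone, Utf1 by -3.06 and Lin28a by -2.57. Their median was -0.68 (camera adjusted p = 0.00938, or 0.266 with an estimated correlation). Fatty acid synthesis genes rose for 3 of 10, with 7 not passing and 5 higher and 1 lower adjusted over the list alone, Me1 by 1.20 and Scd2 by 1.12. Their median was 0.45 (camera adjusted p = 0.0194, or 0.266 with an estimated correlation). Germ cell genes fell for 4 of 21, among them Tdrd1 (-1.58), and Dazl alone rose, with 16 not passing and 5 lower and 1 higher adjusted over the list alone. Their median was -0.52 (camera adjusted p = 0.0208, or 0.667 with an estimated correlation). Spic rose by 5.90 (SE 0.78) and the homeobox gene Vax2 by 5.00 (SE 0.21), and Trpm1 was at least 14.4-fold (adjusted p = 0.00137) and Cyp1a1 at least 22.4-fold higher. Mmp3, well above background on 1 of the 2 day 10 arrays, fell by 6.23 (SE 1.05) and Rxrg by 6.01 (SE 0.30), and the neuropeptide gene Grp was at least 9.01-fold lower (adjusted p = 0.00186).

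By day 10 in the FBS arm 2755 genes had changed, 1617 up and 1138 down, 1941 of them by at least 2-fold (limma). Within slide 1 (Dazl-GFP) the medians of called lists stayed within 1.5 times but for primed and formative genes (-0.66). Blocking on the slide gave 1311, and limma called 0 on the 4 arrays alone (4297 at an unadjusted p under 0.05). The count was 1212 or 670 without replicate 1 or 2 of the FBS day 10 group and 1774 without replicate 1 of the FBS day 0 group. Of the genes changed by day 10, 242 were higher in both arms against 35.2 by chance, 318 lower in both against 34.9 and 8 moved opposite ways.

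**Figure D2:**
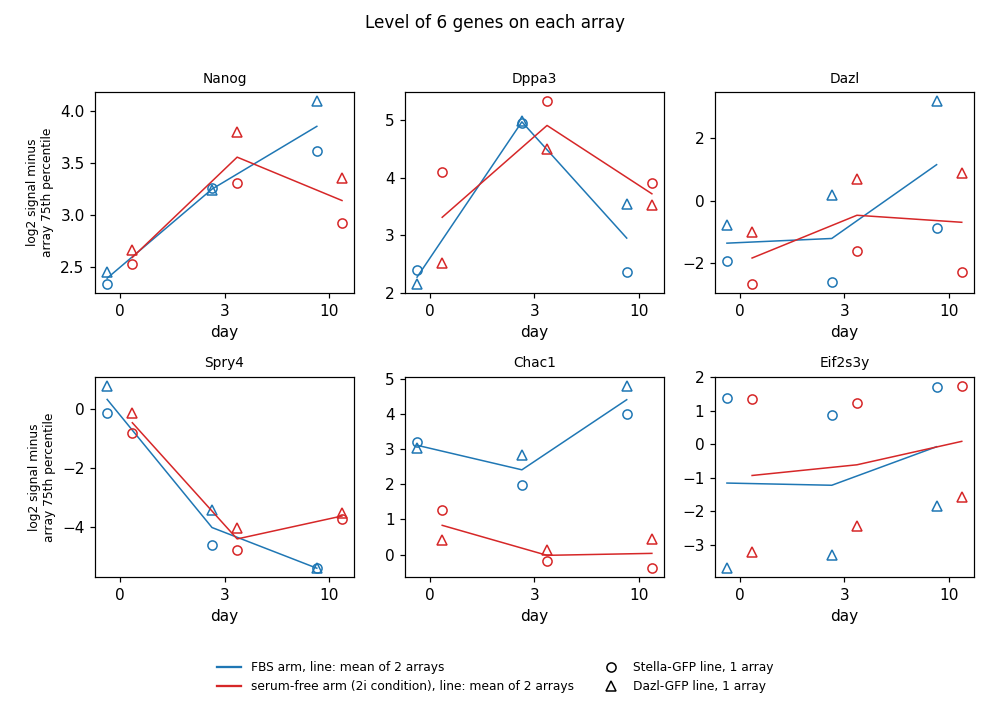
Level of 6 genes on each array (vertical axis, log2 signal relative to the array's 75th percentile) by day (horizontal axis, days at equal spacing) in the FBS and serum-free arms. Circles are Stella-GFP, triangles Dazl-GFP, and lines join the means of the 2 arrays; Spry4 fell by 5.72 in the FBS arm by day 10.

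The difference of the day 10 changes asks where the arms changed unequally. It passed for 14 genes (limma), and the serum-free change minus the FBS change was above 0 for 4 and below 0 for 10. It was 4.92 for Rxrg (SE 0.42, adjusted p = 0.0285) and 3.60 for the neural membrane protein gene Gpm6b (SE 0.39, adjusted p = 0.0461), which both fell in the FBS arm. Figla also passed (adjusted p = 0.0102), with no size given because it was well above background in the FBS arm at day 0 alone. For the protease inhibitor gene Serpinb1a it was -3.71 (SE 0.28, adjusted p = 0.0203) and for the homeobox gene Pitx1 -3.57 (SE 0.38, adjusted p = 0.0461), and both rose in the FBS arm. Camera called 6 lists, though in each 0 genes passed in limma. Naive pluripotency genes had a median of -0.90 (adjusted p = 1.13e-06), with 8 of 14 lower adjusted over the list alone and 8 at an unadjusted p under 0.05. Primed and formative genes had 1.43 (adjusted p = 5.77e-05), with 6 of 12 higher and 6 unadjusted. Primitive endoderm genes had -1.52 (adjusted p = 6.02e-06), with 5 of 13 lower and 6 unadjusted, and ATF4 targets -0.69 (adjusted p = 7.83e-06), with 4 of 14 lower and 6 unadjusted. Germ cell genes had -0.54 (adjusted p = 0.0046; 0.36 with normexp as planned), with 1 of 21 lower and 3 unadjusted, and sterol synthesis genes -0.29 (adjusted p = 0.0161), with 0 of 19 and 5 unadjusted. With an estimated correlation these had adjusted p = 0.476, 0.476, 0.532, 0.532, 0.572 and 0.532. Of these genes Tbx3 was at -2.10 (SE 0.59) and Tcl1 at -1.43, Fgf5 at 3.37 (SE 0.45) and Dnmt3b at 3.28, Sox17 at -3.43 (SE 0.67) and Lama1 at -3.05. Trib3 was at -2.61 (SE 0.34), Mov10l1 at -1.38 (SE 0.25) and Dhcr7 at -0.93 (SE 0.27). Nanog (-0.91), Tet2 (-1.54, adjusted p = 0.0622), Dazl (-1.37), Dppa3 (-0.27), Pou5f1 (0.20), Tet1 (0.38) and Tet3 (-0.18) did not pass. With 1 array left out limma called 0 without replicate 2 of the FBS day 10 group, replicate 1 of the serum-free day 0 group, either serum-free day 3 array or replicate 2 of the serum-free day 10 group (2867 to 4008 at an unadjusted p under 0.05). It called 1 without either FBS day 3 array or replicate 1 of the serum-free day 10 group, 3 without replicate 1 of the FBS or 2 of the serum-free day 0 group, 7 without replicate 1 of the FBS day 10 group and 36 without replicate 2 of the FBS day 0 group. The slide as a block gave 0 (3433 unadjusted) and leaving out day 3 gave 0 (3678 unadjusted). The authors' table gave 235 genes (17.4% higher against 28.6%), quantile normalization 67 (17.9%), a variance trend 266, normexp on repaired backgrounds 332 and the model without the cell line block 1, and no slide held all 4 groups.

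Over all days the comparison asks how the arms differed on average, with 6 arrays per arm, and such a difference need not hold at each day. ATF4 targets were lower in the serum-free arm for 10 of 14, with 4 not passing and 12 adjusted over the list alone, Chac1 by -3.03 (SE 0.38), Trib3 by -2.29 (SE 0.37) and Mthfd2 by -1.50 (SE 0.23). Their median was -0.96 (camera adjusted p = 4.4e-08, or 0.407 with an estimated correlation). Nodal targets were lower for 4 of 7, with 3 not passing and 5 adjusted over the list alone, Lefty1 by -1.91 (SE 0.19). Their median was -0.57 (camera adjusted p = 0.000121, or 0.0857 with an estimated correlation). Retinoid response genes were lower for 6 of 10, with 4 not passing and 6 adjusted over the list alone, Stra8 by -2.85 (SE 0.62), though Stra8 was at 0.33 with the slide as a block. Their median was -0.98 (camera adjusted p = 0.00371, or 0.139 with an estimated correlation). Serum response genes were lower for 9 of 17, with 8 not passing and 12 adjusted over the list alone, Myl9 by -2.29 and Fos by -2.04. Their median was -1.20 (camera adjusted p = 1.64e-06, or 0.555 with an estimated correlation). Fibroblast markers were lower for 6 of 19, with 13 not passing and 6 adjusted over the list alone, S100a4 by -2.81 and Twist2 by -2.35. Their median was -0.87 (camera adjusted p = 7.59e-05, or 0.555 with an estimated correlation). Primitive endoderm genes were higher for 3 of 13, with 10 not passing and 3 adjusted over the list alone, Cubn by 3.06 (SE 0.54) and Sox7 by 1.30. Their median was 0.90 (camera adjusted p = 0.0019, or 0.555 with an estimated correlation), against -0.63 at day 10 alone. The RNA sensor gene Ddx58 was higher by 2.55 (SE 0.23) and Ccl5 by 2.52 (SE 0.47), and Stmn4, which binds tubulin, was lower by -2.90 (SE 0.23). Tet2 (0.75, adjusted p = 0.0803), Dazl (-0.53), Dppa3 (0.58), Nanog (-0.07), Pou5f1 (-0.25), Tet1 (0.18) and Tet3 (-0.54) did not pass. In all 1981 genes differed, 875 higher and 1106 lower (limma). With the slide as a block limma called 0 (3256 at an unadjusted p under 0.05), slide 2 alone held both arms at day 3, and no slide held both at days 0 and 10. The count was 1209 or 982 without replicate 1 or 2 of the FBS day 3 group, 1246 or 1190 without those of the serum-free day 0 group, 1144 or 992 without those of its day 3 group and 1071 without replicate 1 of its day 10 group. It was 266 without day 3, 399 with the fibroblast level as a covariate and 4250 as a mean of the contrasts within a day.

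The lines were compared as 6 arrays against 6. Y-linked genes were lower in the Dazl-GFP line for 3 of 4, with 1 not passing and 3 adjusted over the list alone: the translation factor gene Eif2s3y by -4.06 (SE 0.24), the helicase gene Ddx3y by -2.60 (SE 0.29) and Uty by -2.50 (SE 0.39). In the Dazl-GFP and Stella-GFP lines Uty was well above background on 1 and 5 of 6 arrays and Ddx3y on 5 and 6. Their median was -2.55 (camera adjusted p = 0.000344, or 0.385 with an estimated correlation). Dazl was higher in the Dazl-GFP line by 2.53 (SE 0.36, adjusted p = 0.0156), while its other probe gave 0.85 (adjusted p = 0.154), and Tet2 was higher by 0.50 (SE 0.10, adjusted p = 0.0482), with 0.61 and 0.89 at its other probes. Nanog (0.27), Dppa3 (-0.30), Pou5f1 (0.10), Tet1 (0.05) and Tet3 (-0.06) did not pass. The innate immune sensor gene Nod1 was higher by 3.98 (SE 0.23), the chemokine Ccl27a by 3.19 (SE 0.13) and the lipoprotein gene Apoa2, well above background on 1 of the 6 Stella-GFP arrays, by 4.38 (SE 0.32), and the imprinted transcription factor Plagl1 was lower by -3.27 (SE 0.19). Imprinted genes were lower for 3 of 17, Plagl1 and Nnat (-2.59) among them, with 8 lower and 1 higher adjusted over the list alone (median -0.40, camera adjusted p = 0.0127, or 0.385 with an estimated correlation). Fibroblast markers were lower for 1 of 19, Twist2 by -0.79, with 3 adjusted over the list alone (median -0.40, camera adjusted p = 0.000763, or 0.388 with an estimated correlation). Camera called 8 other lists, at adjusted p from 0.00251 to 0.0249 and adjusted p = 0.385 to 0.509 with an estimated correlation. Serum response genes were lower for 3 of 17, Myl9 by -0.94 and Ankrd1, well above background on 4 of the 6 Dazl-GFP arrays, by -0.87 (5 adjusted over the list alone, median -0.24), Nodal targets for 2 of 7, Tdgf1 by -0.76 among them (3, median -0.34), and primed and formative genes for 1 of 12, Fgf5 by -1.74 (2, median -0.46). Of 5 measured 2-cell stage genes Zscan4c was lower by -2.58 (4 adjusted over the list alone, median -1.07), and of 11 neuroectoderm genes Nes by -0.85 (3, median -0.26). Primitive endoderm genes were higher for 1 of 13, Lama1 by 1.00 (2 adjusted over the list alone, median 0.34). Of 14 naive genes Klf5 was higher by 1.23 and Zfp42 lower by -0.88 (the same adjusted over the list alone, median 0.24). Of 14 ATF4 targets 0 passed in limma, 1 was higher adjusted over the list alone and 3 had an unadjusted p under 0.05 (median 0.27), with Mthfd2 at 0.76 and Trib3 at 0.48. The neuroectoderm median was 0.01 with the slide as a block. In all 574 genes differed, 234 higher and 340 lower in the Dazl-GFP line (limma). With the slide as a block 1 passed, and within slides 1 and 3 the Y-linked median was -3.48 and -2.497 and the Nodal target median -0.45 on both. Medians turned for fibroblast markers on slide 1 (0.49, against -0.84 on slide 3) and on slide 3 for naive (-0.108, against 0.39 on slide 1), primed and formative (0.099, -1.27), neuroectoderm (0.26, -0.435) and primitive endoderm genes (-0.146, 0.92). Medians of serum response, 2-cell, ATF4 and imprinted genes kept their sign, at -0.39, -2.52, 0.12 and -0.22 on slide 1 and -0.25, -0.94, 0.14 and -0.20 on slide 3. The count was 184 without either FBS day 10 array, 187 without either serum-free day 3 array, 201 without either serum-free day 0 array, 278 without either FBS day 3 array and 368 without either serum-free day 10 array. It was 36 without day 3, and normexp on repaired backgrounds gave 1323 with 24.6% higher against 40.8%.

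Whether the arms differed by line was tested as an interaction. Limma called 0 genes, with 2253 at an unadjusted p under 0.05 and a smallest adjusted p of 0.461, the slide as a block called 1, and the other settings gave 0. Camera called MEK-ERK targets (median 0.46) and serum response genes (median 0.31), both at adjusted p = 0.0144 and adjusted p = 0.655 with an estimated correlation. In both lists 0 genes passed in limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, with Myc at 1.497 (SE 0.61) and Dusp6 at 0.92 in the first, Egr2 at 1.06 (SE 0.39) and Fos at 0.91 in the second.

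Camera called 7 lists in none of the 11 comparisons, and their lowest adjusted p-values were 0.0676 (BMP targets), 0.0726 (mesendoderm), 0.0784 (p53 targets and antioxidant response), 0.091 (trophoblast), 0.0956 (glycolysis) and 0.151 (DNA methylation and demethylation).

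**Figure D3:**
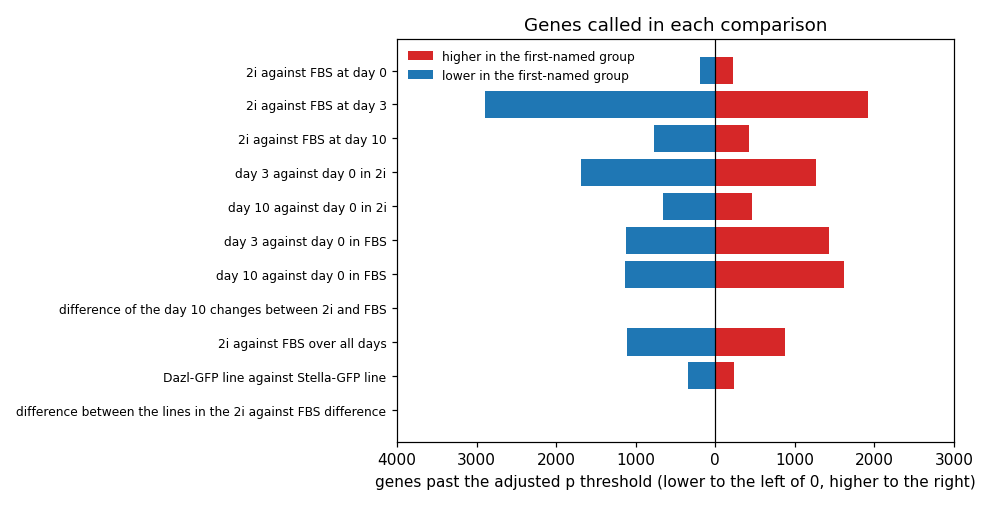
Number of genes (horizontal axis) past an adjusted p of 0.05 in limma in each comparison, with genes higher drawn to the right and genes lower to the left. The most genes, 4814, differed between the arms at day 3.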

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

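The tests of slides for the MEK-ERK targets, of Stella-GFP cells for the Y-linked genes and of other splits were planned, and those of feeder cells, scaling, the slides for fibroblast markers, inhibitors in both arms and the 7 autosomal genes measured on every array were chosen after the result was seen.

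The day 10 change differed between the arms, by the test of the difference itself, for 14 genes. The change in the serum-free arm minus that in the FBS arm was 4.92 for Rxrg and 3.60 for Gpm6b, and -3.71 for Serpinb1a, -3.57 for Pitx1, -3.48 for Serpinb1c, -3.13 for Padi4, -2.75 for S100a13, -2.60 for Hrh1, -2.37 for Qpct and -2.09 for Catsperz. Figla passed too (adjusted p = 0.0102), with no size because 3 of the 4 groups were not well above background. Serpinb1c was well above background on 1 of the 2 FBS day 0 arrays and turned to 0.19 with normexp as planned. By camera with the preset correlation it also differed for naive pluripotency (median -0.90), primed and formative pluripotency (1.43), germ cell genes (-0.54), primitive endoderm (-1.52), sterol synthesis (-0.29) and ATF4 targets (-0.69). With an estimated correlation none of these 6 lists passed, the smallest adjusted p being 0.476. The arms lay mostly on different slides, and the slide as a block left 0 of the 14 (limma, 3433 at an unadjusted p under 0.05).

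Fibroblast markers were lower in the serum-free arm at day 3 for 16 of 19 (median -2.08), a list call that was lost with an estimated correlation (adjusted p = 0.364). Slides alone do not give this, at -2.85 within slide 2 across lines (-2.74 with a slide block). Between lines it was 0.49 and -0.84 on slides 1 and 3. Nor does scaling, as all genes had -0.21 (markers -2.03 after quantile normalization). Fewer feeder cells and an effect of the medium on the same cells cannot be told apart and may have gone together. That 84.2% of the 19 markers lay at least 1 log2 unit below the median of all genes restates the pattern. Acta2 and Tagln are also in the serum response list. The labels name irradiated embryonic fibroblasts in both arms and give no step that removed them.

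MEK-ERK targets were lower at day 10 than at day 0 for 9 of 17 in FBS (1 higher) and 6 of 17 in the serum-free arm. The list calls were lost with an estimated correlation (adjusted p = 0.266 and 0.333). Slides do not give the lower medians, at -1.41 within slide 1 (FBS, Dazl-GFP) and -0.78 within slide 3 (serum-free, Stella-GFP). With the fibroblast covariate they were -1.003 (FBS) and -0.937 (serum-free), but that level moved little by day 10, so feeder cells stay open. The labels leave open whether both arms received the inhibitors after day 0. The FBS medians, -1.06 (Stella-GFP) and -1.41 (Dazl-GFP), restate the pattern, and time in culture was not tested.

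On the Dazl-GFP arrays, 1 per arm and day, the mean level of Eif2s3y and Ddx3y was 4.85% of that on the Stella-GFP array at day 0 and 22.2% at day 10 in the FBS arm, and 8.24% and 16% in the serum-free arm. This rise was not tested within the line, and over both lines camera did not call the Y-linked list by day 10 (adjusted p = 0.243 and 0.155). Fibroblast markers moved by -0.49 and -0.68 on these single arrays, too few to exclude male feeder cells. Stella-GFP cells in the Dazl-GFP samples could give the rise with a share of 17.3% or 7.74%. For 9 autosomal genes higher in the Stella-GFP line the rise was 0.352 (FBS) and 0.685 (serum-free) of that predicted from this share, and 4 of 9 lay under 50% of it in each arm. Of the 9, 2 were not well above background on every array of days 0 and 10, and over the other 7 the ratios were 0.838 and 0.46. Mixing and a rise within the line cannot be told apart, because the values scatter too widely over so few genes on single arrays.

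Of the splits drawn, the real one gave the most genes both over all days and between the lines. Arms and lines lay unevenly on the slides, so this does not exclude slides and chance together. Over all days the real split gave 1981 genes and the highest of the others 1104, so that 1 of 100 splits, the real one, gave as many. That highest split set the 4 arrays of slide 1 and both serum-free day 10 arrays apart from the rest, so it follows the slide in part, and the slide as a block left 0 genes (limma, 3256 at an unadjusted p under 0.05). Between the lines the real split gave 574 genes and the highest of the others 88, again 1 of 100. Among the 32 splits that part all 6 pairs the highest others were 5 and 0.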

How the results depend on the processing

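The repaired normexp, the fibroblast covariate and leaving out day 3 were chosen after seeing the data, and the cause of a change was not tested unless given here. No called gene changed sign when 1 array was left out; an arm left with 1 array was assumed to vary like the other groups. Signal over background limits dim genes, as 64% to 74.4% of the spots lay well above it. Counts of changed genes follow the order of the report: arms at days 0, 3 and 10, serum-free days 3 and 10, FBS days 3 and 10, difference of the day 10 changes, all days, lines, line by arm. In the main analysis they were 406, 4814, 1202, 2955, 1119, 2558, 2755, 14, 1981, 574 and 0. Those not given below stayed within 1.5 times these.

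Normexp as planned gave 0 (2774 at an unadjusted p under 0.05), 109, 8, 64, 0 (1248), 76, 346, 0 (1400), 119, 9 and 0. The cause was 10 spots of the FBS day 0 Dazl-GFP array with a local background up to 61572.5 against a median of 48, which put the fitted background mean at -962 against -5.32 to -14.4 elsewhere. With these repaired (mean -9.25) it gave 1000, 9634, 8520 for FBS day 3, 332 for the difference of the day 10 changes and 1323 for the lines. Quantile normalization gave 67 and the authors' table gave 235 for the difference of the day 10 changes. No filter gave 197, 799 (day 10), 735 (serum-free day 10) and 5 (difference of the day 10 changes). Only genes above background on all 12 arrays, fewer genes by construction, gave 787 at day 0 and 263 for that difference. All probes gave 7530 (day 3), 4594 (serum-free day 3) and 7 (that difference), with more tests by construction.

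Without the cell line block the counts were 143, 613 (day 10), 599 (serum-free day 10), 1596 (FBS day 3) and 1 (difference of the day 10 changes), and the block moved no other count by more than 1.5 times. The slide as a block gave 0 (2822 unadjusted), 1453, 0 (2477), 11 (serum-free day 10), 782 and 1311 (FBS days 3 and 10), 0 for the difference of the day 10 changes (3433), 0 for all days (3256), 1 for the lines and 1 for line by arm. A variance trend gave 898 at day 0, 266 for the difference of the day 10 changes and 994 for the lines. Only the 4 arrays compared, fewer samples by construction, gave 0 at days 3 (7269) and 10 (4162), serum-free day 10 (5162) and FBS days 3 (3757) and 10 (4297). With the fibroblast covariate the counts were 0 (day 3; 5444), 781 (day 10), 1178 (serum-free day 3), 29 (difference of the day 10 changes) and 399 (all days). Without day 3 they were 0 (3678), 266 and 36 for the difference of the day 10 changes, all days and the lines. The mean of the contrasts within a day gave 4250 for all days.

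Leaving out 1 array gave 3 to 229, 1065 to 5784, 15 to 1538, 232 to 4070, 0 to 1444, 315 to 2284, 670 to 2435, 0 to 36, 982 to 1747, 184 to 408 and 0 to 0. Line by arm gave 0 in each other setting but the slide block (1830 to 3477 unadjusted over the scalings and filters). The share higher moved by more than 10 points for day 0 (53.9% to 64.1% quantile, 68.8% authors' table), day 3 (39.8% to 50.8%, 52.7%, 20.3% repaired and 20.2% planned normexp), day 10 (35.7% to 21.9% authors' table, 48.6% repaired, 0% of 8 genes in limma with planned normexp), serum-free day 3 (42.7% to 23.4% planned normexp) and 10 (41.5% to 23.6% authors' table), FBS day 3 (55.9% to 83% repaired), the difference of the day 10 changes (28.6% to 17.9% quantile, 17.4% authors' table), all days (44.2% to 30.3% planned) and the lines (40.8% to 24.6% repaired, 100% of 1 gene with the slide block). The median of all genes moved by more than 0.1 at day 0 (-0.02 to 0.14 authors' table, -0.45 planned normexp) and day 3 (-0.21 to -0.077 quantile, -0.092 authors' table, -0.32 both normexps, -0.43 covariate). It did so too at day 10 (0.11 to 0.001 authors' table), serum-free days 3 (-0.04 to -0.18 covariate) and 10 (0.12 to -0.062 authors' table) and FBS days 3 (0.09 to 0.30 repaired, -0.38 planned) and 10 (-0.03 to -0.47 planned). For the difference of the day 10 changes it was 0.48 planned and -0.19 authors' table, for all days -0.22 planned and -0.18 slide block, for the lines 0.11 planned, and for line by arm -0.36 planned, 0.18 authors' table and 0.10 slide block.

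Medians of lists turned with the fibroblast covariate for LIF-STAT3 targets at days 3 (0.016) and 10 (0.099) and for fibroblast markers, which the covariate holds level by construction, at day 3 (0.055), day 10 (0.135), serum-free day 10 (0.037), all days (0.125) and lines (0.048). They turned for primitive endoderm at day 10 without replicate 2 of the serum-free day 10 group (0.034, against -1.192 without replicate 1), germ cell genes in the difference of the day 10 changes with planned normexp (0.36) and neuroectoderm between the lines with the slide block (0.006). Within a slide 7 medians of called lists turned: 2-cell stage genes in FBS by day 3, fibroblast markers by serum-free day 10, and 5 lists between the lines, with the values in the report. Genes that turned with planned normexp were Iigp1 (-0.20), Rspo2 (-0.42), Serpina3n (-0.37) and Sly (-0.56) at day 0, Peg10 (-0.066, the same when repaired) at day 3, Ffar2 (-0.43) and Nanos3 (-0.017) in FBS by day 3, Cd3d (-0.30), Map2 (-0.011), Pla2g4e (-0.10) and Slc7a11 (-0.49) in FBS by day 10, Serpinb1c (0.19) in the difference of the day 10 changes and Gata4 (-0.23) over all days. Others were Sycp2 with repaired normexp (0.042, FBS day 3), Stard4 over all probes (-0.58 at day 3, -0.51 serum-free day 3), Gadd45b (0.68) and Osmr (0.14) with the covariate at day 3, and Dhrs3 (0.59) and Stra8 (0.33) over all days with the slide block. Of 478 calls of named genes 462 were kept with quantile normalization, 454 in the authors' table, 473 with a variance trend, 447 with repaired and 81 with planned normexp, 413 with no filter or all probes, 285 with the covariate, 176 with the slide block and 313 to 412 with 1 array left out. Kept were 360 of 360 with genes above background on all arrays, 335 of 442 without the cell line block, 75 of 388 on the 4 arrays alone, 34 of 90 without day 3 and 43 of 43 as a mean of contrasts.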

Other observations

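The gene lists here were chosen after seeing the data, and so were their tests. Each list leaves out the genes that had prompted it, Cyp1a1 among them. Of 28 interferon response genes 8 were higher in the serum-free arm at day 10 and 20 did not pass, Gbp3, well above background on 1 of the 2 FBS arrays, by 3.20, Irf7 by 2.37, Rsad2 by 2.26 and Bst2 by 1.93, with a median of 1.09 (camera adjusted p = 2.79e-08, adjusted p = 0.253 with an estimated correlation). At day 0, 2 of 28 were higher, Irf9 by 1.26 and Gbp2 by 1.05, with a median of 1.10 (camera adjusted p = 1.43e-06, adjusted p = 0.354 with an estimated correlation). At day 3 the median was -0.17 and 2 of 28 were lower. Camera also called the list by day 3 in the FBS arm (9 of 28 rose and 2 fell, median 0.91), over all days (median 0.61), between the lines (-0.088) and for line by arm (0.22), at adjusted p = 0.00555, 1.01e-06, 0.0429 and 0.0051, and at 0.438 to 0.774 with an estimated correlation.

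Macrophage genes at day 3 were lower in the serum-free arm for 6 of 17, among them the complement gene C1qa by -2.75 and the surface receptor gene Adgre1 by -2.62, and higher for 2, with a median of -0.87 (camera adjusted p = 0.123). Aryl hydrocarbon receptor targets rose by day 10 in the FBS arm for 2 of 9, Cyp1b1 by 1.79 and Nqo1 by 1.76, with a median of 0.53 (camera adjusted p = 0.045, adjusted p = 0.174 with an estimated correlation). By day 3 in that arm 2 of 9 rose (median 0.155, camera adjusted p = 0.457). In the serum-free arm 1 of 9 rose by day 3 (median 0.25, camera adjusted p = 0.825), and by day 10 0 of 9 passed in limma, 4 at an unadjusted p under 0.05 (median 0.73, camera adjusted p = 0.351).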
